A study of Arabidopsis thaliana with 5 samples.

How the data were processed

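RNA-seq of total RNA from Arabidopsis thaliana roots gave 5 libraries, which form 5 groups of 1 library each: a control at 4 d, low Mg (0.5 µM) at 4 d, high Mg (10 mM) at 4 d, low Mg at 7 d and high Mg at 7 d. The groups were taken from the sample titles. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), made by the authors for 33559 loci of the TAIR10 gene set. No label names this unit: it was read from the submitters' tool list for the 4-d samples and from the spacing of low values in all 5 libraries. The submitters' processing notes list TopHat2 2.0.8, Cufflinks 2.1.1 and TAIR10 for the 4-d samples and TAIR10 alone for the 7-d samples, whose aligner and counting tool are not given in the sources used here. Whether the authors scaled the libraries to one another, and whether the libraries kept strand information, is likewise not given in those sources. Every value of the series' matrix was identical to that of the sample's own table.

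Per gene, the ratio of libraries a and b was computed as log2((a + 1)/(b + 1)) on the deposited FPKM, with a pseudocount of 1 and no further scaling. Nuclear genes (33280 loci) with 5 FPKM or more in at least one of the libraries compared were kept, and a log2 ratio of 1 or more, or -1 or less, counted as a 2-fold difference. The 133 chloroplast and 146 mitochondrial loci were left out of the comparisons. With 1 library per group there is no replicate error, so no p-value, standard error or call of significance was computed. Symbols, biotypes and coordinates came from the TAIR10.1 annotation, in which 32817 loci (97.8%) were found by locus tag. The deposited tables carry no coordinates, so positions are those of TAIR10.1 and not of the authors' own annotation.

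For 27 gene lists fixed before the data were examined, the median log2 ratio of the measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins of genes. A median below percentile 2.5 or above 97.5 was called outside the random range. This places a list among the genes of these libraries and says nothing about other roots. A list with fewer than 3 measured members got no percentile. Of 369 list entries, 7 were left out because the annotation does not pair the symbol and the locus, and 1 shared its locus with another entry of its list. Ratios at 4 d and at 7 d, and ratios of low and high Mg to the shared control, were set against each other by Pearson and Spearman correlation across genes and by overlap of the 2-fold genes. The overlap of independent lists was the product of the numbers of genes divided by all genes compared. It takes every gene as equally likely to reach 2-fold, so genes with variable values alone can raise an overlap above it. For the shared control, values were also simulated for 3 libraries with a common true level and noise resampled from the observed ratios. That noise holds any effect of Mg, so the simulation does not isolate what sharing a library produces.

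Genes named in the text follow a rule fixed before the data were examined: the 8 highest and 8 lowest genes with a symbol in each of the 4 comparisons of Mg levels, up to 3 highest and 3 lowest list members at 2-fold or more, the 8 highest and 8 lowest of the genes 2-fold apart the same way on both days, and 5 genes each that lay the same way and opposite ways in low and high Mg at 4 d. Lists on Mg2+ transport and root hairs were to be described in any case, so members short of a 2-fold difference are named for them, as they are for other lists where stated. The first part of the rule picked mostly short or non-coding RNA genes listed at 0 in 1 library. After seeing the data, the same part was therefore also run on protein-coding genes with an exon length of 500 nt or more, and the leading genes given are from that run. Genes listed at 0 in a library get no fold.

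Library size was estimated from the lowest mode of FPKM times exon length over protein-coding genes with an exon length of 2000 nt or more, taken as the value of 1 fragment. The estimates were 11.2 M fragments (control), 13.6 M (low Mg, 4 d), 12.8 M (high Mg, 4 d), 7.33 M (low Mg, 7 d) and 11.9 M (high Mg, 7 d). Fragments per gene derived from these sizes are approximate and speak of counting error only. They do not hold for short genes: of genes under 250 nt within about 10-fold of the lowest value at the same exon length, 17 of 25 in the control and 27 of 52 in high Mg at 7 d were whole multiples of it. A high FPKM on such genes can stand for 1 or a few fragments, so fragments were not estimated under 500 nt, and the short RNA genes picked by the rule are not described. This was seen only after the data were examined. The procedure was tested on simulated data with Poisson noise alone: all 50 of 50 genes were found at each true ratio of 0.25, 0.4, 2.5 and 4, and 0 of 15404 unchanged genes. The changed genes were drawn well above the filter, and both libraries had the same size. Fragments were taken as FPKM times length for short genes too. The simulation therefore says nothing about changed genes near the filter, about short genes or about noise between plants. Of 200 random lists in that simulation, 6.5% fell outside the random range.

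Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and filters of 1 and 20 FPKM, median centring, rescaling of each library to the same sum of nuclear genes (TPM), upper-quartile scaling, a 4-fold threshold and the inclusion of organelle genes. Added after seeing the data were TPM without the locus AT2G01021 and protein-coding genes of 500 nt or more alone. Low against high Mg at 4 d was a comparison fixed beforehand, and it also serves as the one without the control library. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.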

Results

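Gene expression was measured in roots of Arabidopsis thaliana, given as Col-1 in the labels, from plants grown for 5 weeks and then supplied with little or much magnesium. The 5 groups were a control at 4 d, low Mg (0.5 µM) at 4 d and 7 d, and high Mg (10 mM) at 4 d and 7 d. The Mg level of the control is not in the labels, and no control at 7 d was used here. Each group is 1 library, so there are no replicates and no replicate check, and each difference is one between single libraries. The series concerns the effect of Mg supply on the development of root hairs, the tubular outgrowths of root epidermal cells.

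Loci above 0 numbered 22349 in the control, 22533 in low Mg at 4 d, 22397 in high Mg at 4 d, 21873 in low Mg at 7 d and 22638 in high Mg at 7 d. At the estimated library sizes, 5 FPKM for a transcript of 1 kb stood for between 36.6 fragments (low Mg, 7 d) and 68.1 fragments (low Mg, 4 d). Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.976 to 0.982 between the 4-d libraries, 0.977 between the 7-d libraries and 0.947 to 0.959 between days. The 102-nt locus AT2G01021 held 82.3% of the summed FPKM in the control, 75.5% in low Mg at 4 d and 57.5% in high Mg at 4 d, but 18.5% and 15.6% in low and high Mg at 7 d. Rescaling to the same nuclear sum (TPM) therefore moved the median log2 ratio of all genes by 0.38 for low Mg and by 1.04 for high Mg against the control, and by -0.66 for low against high Mg at 4 d. At 7 d the corresponding shift for low against high Mg was -0.07. The locus is very short, and at such lengths a high FPKM can stand for few fragments. Its fragments were not estimated, so its share of the summed FPKM is not a share of the fragments. Ratios without the TPM rescaling are given throughout. Because it moves all genes, a median it turned says little of the list itself, so it is also stated whether the list kept its place outside the random range.

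Low Mg against the control at 4 d sets 1 library with 0.5 µM Mg beside 1 control library, so a difference can also lie with the control. Several genes of calcium and stress signalling were higher in low Mg. The calmodulin-like genes CML37 and CML38 stood at 38.1 and 39.4 FPKM against 5.75 and 7.26 FPKM in the control, the transcription factor gene WRKY46 at 40.1 against 5.61 FPKM, and CAF1a, which encodes an mRNA deadenylase, at 122 against 7.65 FPKM. IRT1, the iron uptake transporter of the root epidermis (AT4G19690, TAIR10.1 chromosome 4, 10707344 to 10709015), was higher at 81.0 against 25.5 FPKM, a log2 ratio of 1.63. The high-affinity nitrate transporter gene NRT2.1 (AT1G08090, chromosome 1, 2524023 to 2526322) was lower at 135 against 1341 FPKM, a log2 ratio of -3.30.

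Of 15873 genes compared in low Mg and control, 343 were at least 2-fold higher and 265 at least 2-fold lower, and 104 of these 608 were listed at 0 in 1 of the libraries. Other leading coding genes that were higher were RTFL12, a small peptide gene (log2 3.23), ERF13, an ethylene response factor (3.07), DIR5, a dirigent protein (2.66), and DIC2, a mitochondrial dicarboxylate carrier (2.62). RTFL18 (74.6 FPKM) and LCR43 (11.9 FPKM) were listed at 0 in the control. Lower were the leucine-rich repeat gene PIRL8 (-3.35), the heat shock genes HSP70 (-3.04) and HSP90.1 (-2.96), and the expansin EXPA17 (-2.99). The phosphate transporter gene PHT1;3 (47.2 FPKM in the control), CDT1 (AT1G52827, 7.51 FPKM) and SAUR29 (5.79 FPKM) were listed at 0 in low Mg. PHT1;3 (AT5G43360) and PHT1;1 (AT5G43350) are neighbouring paralogs, between which fragments can be shared.

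Mg2+ transport genes differed little in low Mg: 0 of 17 measured members reached 2-fold, and their median of -0.05 lay within the random range. The vacuolar cation exchanger genes CAX1 and CAX3 stood at 14.6 and 7.41 FPKM against 20.1 and 11.5 FPKM. Of 26 measured root hair outgrowth and wall genes, 0 reached 2-fold, yet their median of -0.20 lay below the random range. The TPM rescaling turned it to 0.28, still below the random range of that scaling. The hair-cell expansin EXPA7 stood at 35.9 against 55.4 FPKM. Root hair transcription factors (median -0.11 over 7 genes) and non-hair fate genes (-0.05 over 7 genes) had 0 members at 2-fold and lay within the random range.

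Among stress and hormone lists, 4 medians lay above the random range in low Mg. Reactive oxygen genes had 3 of 14 members higher and 1 lower (median 0.38, above the random range), with GSTU24 at 1.87, ZAT12 at 1.85, OXI1 at 1.75 and the iron superoxide dismutase FSD1 at -1.89. Touch and calcium genes had 4 of 13 members higher (median 0.28, above the range), among them TCH4 at 1.35. The jasmonate list had 2 of 5 members higher (0.93, above the range), JAZ1 at 1.97 and JAZ5 at 1.77. The salicylate and defence list had 2 of 10 higher and 1 lower (0.36, above the range), with WRKY40 at 29.8 against 5.70 FPKM, WRKY70 at 1.60 and PR2 at -2.52. Ethylene genes had 2 of 11 members higher, the synthesis gene ACS6 at 1.96 and ERF2 at 1.86, with a median of 0.06 within the range.

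Iron genes in low Mg differed from the control both ways, while the medians of nitrate and phosphate genes were below 0 in low and in high Mg. The iron deficiency list had 4 of 14 members higher and 2 lower, with CYP82C4 at 12.1 against 1.66 FPKM, the ferritin gene FER1 at 1.89, the regulator bHLH39 at -2.22 and the transporter OPT3 at -2.13. The list's median of 0.28 lay above the random range but was -0.0440, within the range, with no filter on low values. FER1 serves iron storage, so its rise is counted as higher without speaking for a shortage of iron. Nitrate genes had 1 of 10 higher and 3 lower, NIA2 at 1.02, NRT3.1 at -1.42 and NRT1.5 at -1.05 among them, and their median of -0.44, below the range, turned to 0.0415 under the TPM rescaling but stayed below the range. Phosphate genes had 1 of 10 lower, PAP17 at -1.57 (median -0.35, below the range). In low against high Mg at 4 d the nitrate and phosphate medians were -0.09 and -0.03, within the range. In these lists the medians of low and high Mg thus lay on the same side of the control. With 1 control library, a response shared by both Mg levels and a control that stands apart cannot be told apart. The sulfate list had APR3 higher at 1.01 (1 of 6 members, median 0.20, above the range). Within the random range were the potassium list (-0.05), with 1 of 10 higher, HAK5 at 1.15, and the sugar list (0.04), with SWEET12 at 1.57 and BGLU30 at -1.40. The abscisic acid list (-0.18), with RD22 at -1.12, and the flavonoid list (-0.15), with FLS1 at 1.31, also lay within it.

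Tissue markers in low Mg stayed short of 2-fold. Xylem wall genes had a median of 0.23, above the random range, while suberin (0.02), phloem (0.07), meristem (0.15), clock (0.00) and reference genes (-0.05) lay within it. The hypoxia list had 1 of 11 lower, SAD6 at -1.08 (median -0.13, within the range). Heat shock genes were mostly lower in low Mg than in the control: 6 of 8 measured members were lower and 1 higher, with a median of -2.51 below the range. HSP17.4 stood at -2.75 and BIP3, a chaperone of the endoplasmic reticulum, at 1.64. Only 1 of 14 photosynthesis genes of the shoot, LHCA1, passed the filter on low values in this comparison, at 4.67 against 5.74 FPKM.

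High Mg against the control at 4 d sets 1 library with 10 mM Mg beside the same control library, and no test assigns the differences to the excess of Mg. Several root hair wall genes and the potassium transporter gene HAK5 were higher in high Mg. PRP1, a proline-rich wall protein of root hairs (AT1G54970, chromosome 1, 20504901 to 20506504), stood at 41.6 against 0.242 FPKM, from about 729.9 and 3.71 fragments. RSL4, a transcription factor that drives hair growth (AT1G27740, chromosome 1, 9654475 to 9656089), was higher by a log2 ratio of 2.38, from about 172 against 16.9 fragments. HAK5, of high-affinity uptake (AT4G13420, chromosome 4, 7796782 to 7802251), was higher at 184 against 10.2 FPKM (4.05), and IRT1 at 185 against 25.5 FPKM (2.82). CYP71A12, of camalexin synthesis (AT2G30750, chromosome 2, 13099486 to 13101371), was lower at 5.27 against 167 FPKM (-4.75).

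Among 15962 genes compared in high Mg and control, 402 were at least 2-fold higher and 612 at least 2-fold lower, with 120 of them listed at 0 in 1 library. Leading coding genes that were higher also included AIR1, an auxin-induced root gene, at 4037 against 245 FPKM, the annexin ANNAT4 (log2 3.76), EARLI1 (3.75), the thalianol pathway gene CYP705A5 (3.67), PR-1-LIKE (3.31) and the methyl esterase MES17 (3.29). Lower were NRT2.1 (-4.88), HSP17.4 (-4.05), CYP71B22 (-4.04) and HSP70 (-3.98). PHT1;3, GDU6 (13.7 FPKM in the control) and the defence lipase GLIP1 (13.6 FPKM) were listed at 0 in high Mg.

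The Mg2+ transport list had 1 of 18 members higher and 2 lower in high Mg, with a median of 0.13 within the random range. CIPK9, a kinase of the vacuolar Mg2+ pathway (AT1G01140, chromosome 1, 64166 to 67774), stood at 8.35 against 0.713 FPKM, from about 198 and 14.8 fragments. CAX3 was lower at 2.49 against 11.5 FPKM and CAX1 (AT2G38170, chromosome 2, 15989083 to 15993326) at 9.35 against 20.1 FPKM. Of 28 root hair outgrowth genes, 7 were higher and 1 lower, and their median of 0.48 lay above the random range. Examples are RHS18 at 2.48, the extensin EXT12 at 2.37 and, on the low side, RHS15 at -1.54. Of the 8 root hair transcription factors only RSL4 reached 2-fold (median 0.02), and of the 7 non-hair fate genes 0 did (0.10), both within the range.

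Defence genes were lower in high Mg than in the control. The salicylate and defence list had 5 of 10 members lower, with CYP71A13 at -2.80, PR2 at -2.61 and FRK1 at -2.03, and its median of -1.02 lay below the random range, as it did under the TPM rescaling, which moves all genes and turned it to 0.49. The jasmonate list had 2 of 5 higher (0.63, above the range), JAZ1 at 1.32 and VSP1 at 7.17 against 2.80 FPKM. Reactive oxygen genes had 2 of 14 higher and 1 lower (0.17, above the range), GSTU24 at 2.59, OXI1 at 1.63 and FSD1 at -1.31. Auxin genes had 2 of 15 higher (0.22, above the range), LBD29 at 1.73 and IAA19 at 1.07. Within the range lay the touch and calcium list (0.15), with TCH3 at -1.88 and CML9 at -1.09, although CML9 turned to 0.19 under the TPM rescaling. The ethylene list (-0.16), with ACS2 at -1.21, and the abscisic acid list (0.00), with RD22 at -1.01, also lay within it.

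The iron deficiency list had 5 of 14 members higher and 1 lower in high Mg, with CYP82C4 at 3.25, the reductase FRO2 at 1.99 and OPT3 at -1.82. Its median of 0.65 lay above the random range but was -0.11, within the range, with no filter on low values. Medians below the range that turned positive under the TPM rescaling belonged to nitrate (-0.30), phosphate (-0.35), sugar starvation (-0.36), suberin (-0.24) and phloem genes (-0.28, at percentile 2.45). Under that rescaling nitrate, phosphate and sugar genes stayed below the range, and suberin and phloem genes came to lie within it. Their 2-fold members beside NRT2.1 were NRT3.1 at -1.91 and NRT1.5 at -1.51, PAP17 at -1.42, and BGLU30 at -2.07, ASN1 at -1.30 and SWEET12 at 1.34. Sulfate genes had 0 of 6 at 2-fold (-0.15, within the range). The potassium list had HAK5 alone at 2-fold (0.12, within). Flavonoid genes had 4 of 10 higher (0.15, within), with F3H at 2.37, the chalcone synthase gene TT4 at 2.31 and FLS1 at 1.93. Hypoxia genes had 2 of 11 higher and 1 lower (0.13, within), ADH1 at 1.60, PDC1 at 1.30 and HRA1 at -1.03.

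Xylem (0.08), meristem (0.09), clock (-0.04) and reference genes (-0.05) had 0 members at 2-fold in high Mg and lay within the random range. LHCA1 was again the 1 shoot gene past the filter, at 4.73 against 5.74 FPKM. Heat shock genes had 6 of 7 measured members lower in high Mg than in the control (median -2.64, below the range), HSP90.1 at -3.52 among them. The control library thus held HSP70 at 287 FPKM, against 17.2 FPKM in high Mg, beside its high NRT2.1.

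**Figure D1:**
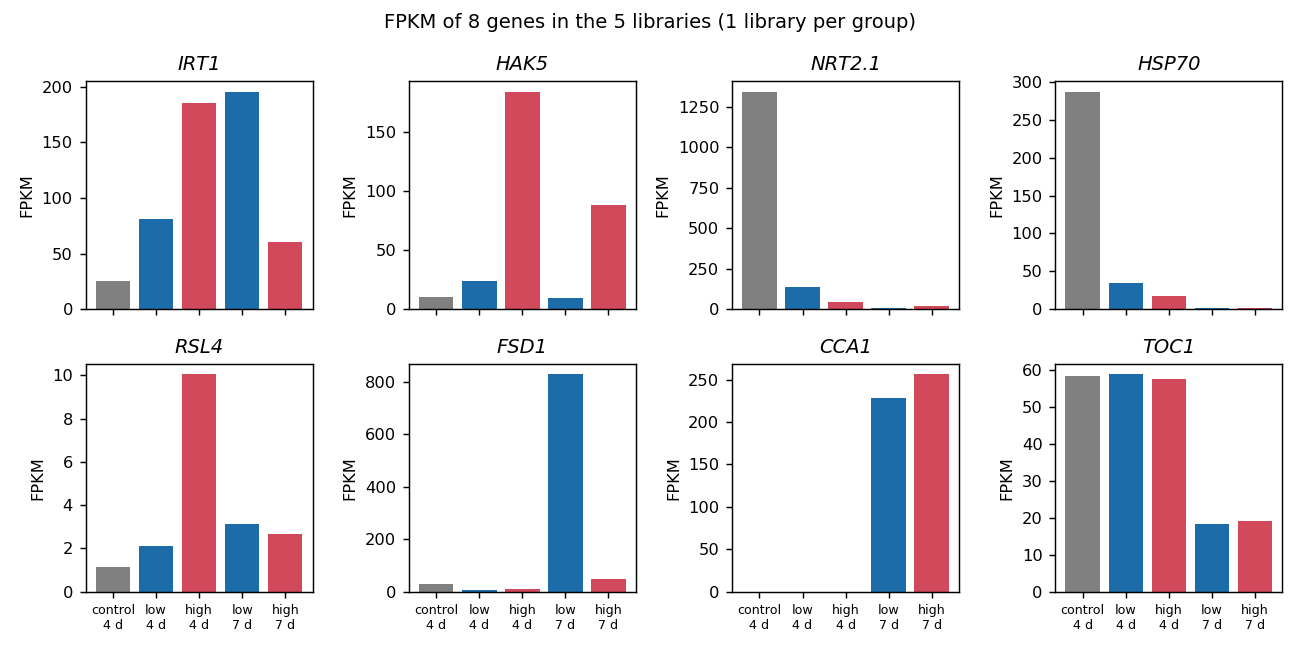
Expression in FPKM (vertical axes, starting at 0, with a scale of their own) of IRT1, HAK5, NRT2.1, HSP70, RSL4, FSD1, CCA1 and TOC1 in the 5 libraries (horizontal axes), each bar being 1 library and having no error. The control alone holds high NRT2.1 (1341 FPKM) and HSP70 (287 FPKM), and the 7-d libraries alone hold high CCA1 (228 and 256 FPKM).

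Low against high Mg at 4 d compares the extremes of supply within a day and does without the control library. Several root hair wall genes were lower in low than in high Mg: PRP1 stood at 1.07 against 41.6 FPKM (log2 -4.36), the xyloglucan endotransglucosylase XTH13 at 1.27 against 13.9 FPKM (-2.71) and EXT12 at 37.9 against 195 FPKM (-2.33). Several defence genes were higher in low Mg, among them CYP71A12 at 246 against 5.27 FPKM (5.30) and WRKY70 (AT3G56400, chromosome 3, 20908711 to 20910623) at 37.9 against 5.74 FPKM (2.53). HAK5 was lower at 23.9 against 184 FPKM (-2.90), and the auxin-induced AIR1 (AT4G12550, chromosome 4, 7439115 to 7439805) at 611 against 4037 FPKM (-2.72).

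In that comparison 585 of 15837 genes were at least 2-fold higher in low Mg and 285 at least 2-fold lower, and 103 of these were listed at 0 in 1 library. Higher coding genes also included CYP71B22 (4.54), the glutathione transferase GSTU12 (4.09), the indole glucosinolate gene IGMT4 (3.56), WRKY30 (31.4 against 1.87 FPKM) and NAC042 (3.39). Lower ones included PR-1-LIKE (-3.37), EARLI1 (-3.12), the tyrosine aminotransferase TAT3 (-3.12), the polygalacturonase PGAZAT (-2.84) and MES17 (-2.75). RTFL18 and LCR43 were listed at 0 in high Mg.

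Of 18 Mg2+ transport genes, 1 was higher in low Mg at 4 d, CAX3 at 1.27, and 1 lower, CIPK9 at -2.39. The median of -0.15 lay below the random range at percentile 1.65, with the MRS2 channel genes between -0.37 (MRS2-7) and -0.02 (MRS2-3). Root hair outgrowth genes had 8 of 29 members lower and 1 higher, RHS15 at 11.0 against 4.61 FPKM, and their median of -0.69 was below the range. Root hair transcription factors had RSL4 lower at -1.84 (1 of 7, median -0.22), and non-hair fate genes had 0 of 7 at 2-fold (-0.22), both just below the range. The Mg2+ transport, transcription factor and non-hair fate lists lay within the range under the TPM rescaling and with a filter of 20 FPKM.

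**Figure D2:**
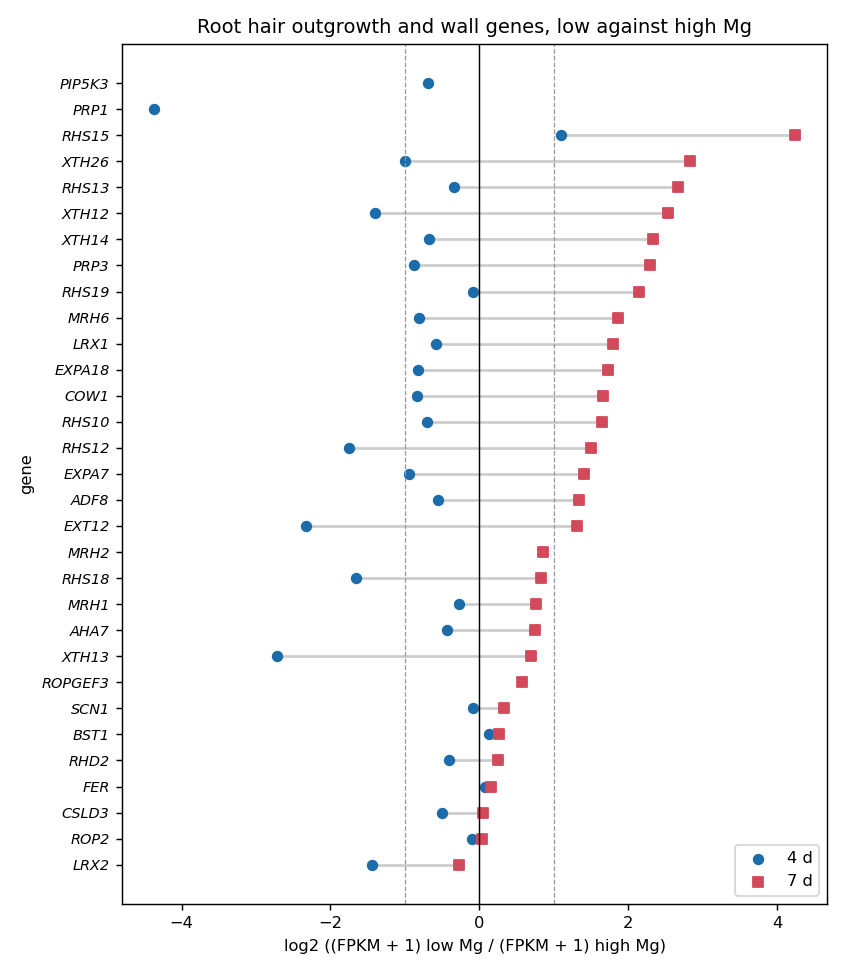
Log2 ratio of low to high Mg (horizontal axis) of each measured root hair outgrowth and wall gene (vertical axis) at 4 d (blue circles) and at 7 d (red squares), 1 library per point and condition, with dashed lines at 2-fold. The median of the list is -0.69 at 4 d and 1.34 at 7 d.

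Defence and hormone lists parted low from high Mg at 4 d. The salicylate and defence list had 6 of 8 members higher in low Mg, with a median of 1.82 above the random range, FRK1 at 2.25 and MYB51 at 2.17. Touch and calcium genes (0.18, 4 of 13 higher, CML37 at 2.83, TCH3 at 2.39), jasmonate genes (0.44, 0 of 6 at 2-fold) and ethylene genes (0.15, 3 of 11 higher, ERF2 at 2.41, ACS6 at 1.83) lay above the range, and all 3 medians turned negative under the TPM rescaling, where touch and jasmonate genes stayed above the range and ethylene genes came to lie within it. Auxin genes had 2 of 15 lower (-0.26, below the range), LBD29 at -1.43 and GH3.5 at -1.11. Reactive oxygen genes had 1 of 14 higher, ZAT12 at 1.27 (0.02, within the range). Only 2 abscisic acid genes, ABI1 and HAB1, were measured, at 0.21 and -0.18.

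Below the random range in low against high Mg at 4 d were the iron list (-0.21, 3 of 14 lower, FRO2 at -1.35, bHLH39 at -1.31, IRT1 at -1.18), the potassium list (-0.19, HAK5 alone at 2-fold) and the hypoxia list (-0.33, SAD6 at -1.21 and PDC1 at -1.13 of 11). Sulfate (0.38), sugar starvation (0.31) and suberin genes (0.19) had 0 members at 2-fold and lay above the range, as did heat shock genes (0.56, 2 of 7 higher, HSP17.4 at 1.30 and BIP3 at 1.19), and all 4 medians turned negative under the TPM rescaling, where only heat shock genes came to lie within the range. Lists within the range were nitrate (-0.09, NRT2.1 higher at 1.58), phosphate (-0.03), flavonoid (-0.10, F3H at -1.51 and TT4 at -1.37), xylem (0.16), phloem (0.22), meristem (-0.09), clock (0.05) and reference genes (-0.01). Of the shoot genes, 0 of 14 passed the filter.

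Low against high Mg at 7 d asks the same of roots treated for longer. Many root hair outgrowth genes were now higher in low Mg: RHS13 stood at 296 against 45.8 FPKM (log2 2.67), XTH26 (AT4G28850, chromosome 4, 14244290 to 14246037) at 51.2 against 6.36 FPKM (2.83), and RHS15, a glycerol-3-phosphate permease gene (AT4G25220, chromosome 4, 12920742 to 12922885), at 51.9 against 1.78 FPKM (4.25). Several genes of iron and copper uptake were higher in low Mg as well. The metal reductase FRO5 (AT5G23990, chromosome 5, 8105461 to 8108642) stood at 382 against 0.693 FPKM, the copper transporter COPT2 (AT3G46900, chromosome 3, 17268700 to 17269510) at 322 against 13.1 FPKM and IRT1 at 195 against 60.0 FPKM. The iron superoxide dismutase FSD1 (AT4G25100, chromosome 4, 12884300 to 12887011) stood at 827 against 47.7 FPKM, and the copper/zinc enzyme CSD1 (AT1G08830, chromosome 1, 2827060 to 2829315) at 80.3 against 734 FPKM.

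At 7 d, 398 of 15684 genes were at least 2-fold higher in low Mg and 504 at least 2-fold lower, with 101 of them listed at 0 in 1 library. Leading coding genes on the high side were also FRO4 (4.50), NRT2.7 (3.69), the malate transporter ALMT1 (3.36) and the arabinogalactan protein FLA6 (3.19). Those on the low side were TAT3 (AT2G24850, chromosome 2, 10582074 to 10585216) at -4.49, scpl14 (-3.77), the heme oxygenase HO4 (-3.76), ARD3 (-3.48), HOL2 (-3.32), HAK5 (-3.05) and CYP705A5 (-2.90). FRO4 and FRO5 are neighbouring paralogs, between which fragments can be shared.

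The Mg2+ transport list at 7 d had 2 of 18 members higher in low Mg, CAX1 at 1.57 and CAX3 at 1.00, and 1 lower, CIPK9 at -1.24, with a median of -0.04 within the random range. Of 29 root hair outgrowth genes, 16 were higher and 0 lower in low Mg, and the median of 1.34 lay above the range. Root hair transcription factors had 2 of 7 higher, ETC1 at 1.06 and LRL3 at 1.01 (0.02, within), and non-hair fate genes had 0 of 7 at 2-fold (-0.09, within). Beside these, the 9 reference genes had a median of 0.36, above the range, with 0 members at 2-fold.

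The iron list had 7 of 14 members higher in low Mg at 7 d, with a median of 1.00 above the random range, FRO2 at 1.66 and CYP82C4 at 1.61. Reactive oxygen genes had 1 of 13 higher, FSD1, and 2 lower, CSD1 at -3.18 and CSD2 at -2.22 (-0.24, below the range). Nitrate (0.37), auxin (0.20), xylem (0.36) and meristem genes (0.26) had 0 members at 2-fold and lay above the range. Hypoxia (-0.23) and suberin genes (-0.22) had 0 at 2-fold and lay below it, although the suberin median turned to 0.28 with a filter of 20 FPKM.

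Within the random range at 7 d were the salicylate (-0.16), ethylene (0.17), abscisic acid (-0.09), flavonoid (-0.15) and phloem lists (-0.03), with 0 members at 2-fold. The same held for 3 measured heat shock genes (-0.20). Also within it were touch and calcium (0.16, CML38 at -1.08), jasmonate (-0.10, JAZ5 at -1.06), phosphate (-0.19, SPX1 at -1.05), sulfate (-0.29, SULTR1;1 at 1.06 and LSU2 at -2.41), potassium (0.13, HAK5 alone), sugar starvation (0.18, DIN10 at 1.81 and ASN1 at -1.06) and clock genes (-0.07, ELF4 at 1.37). Of the shoot genes 2 were measured, and both were lower in low Mg: PSBO1 at 5.43 against 17.7 FPKM and RCA at 2.31 against 5.73 FPKM.

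**Figure D3:**
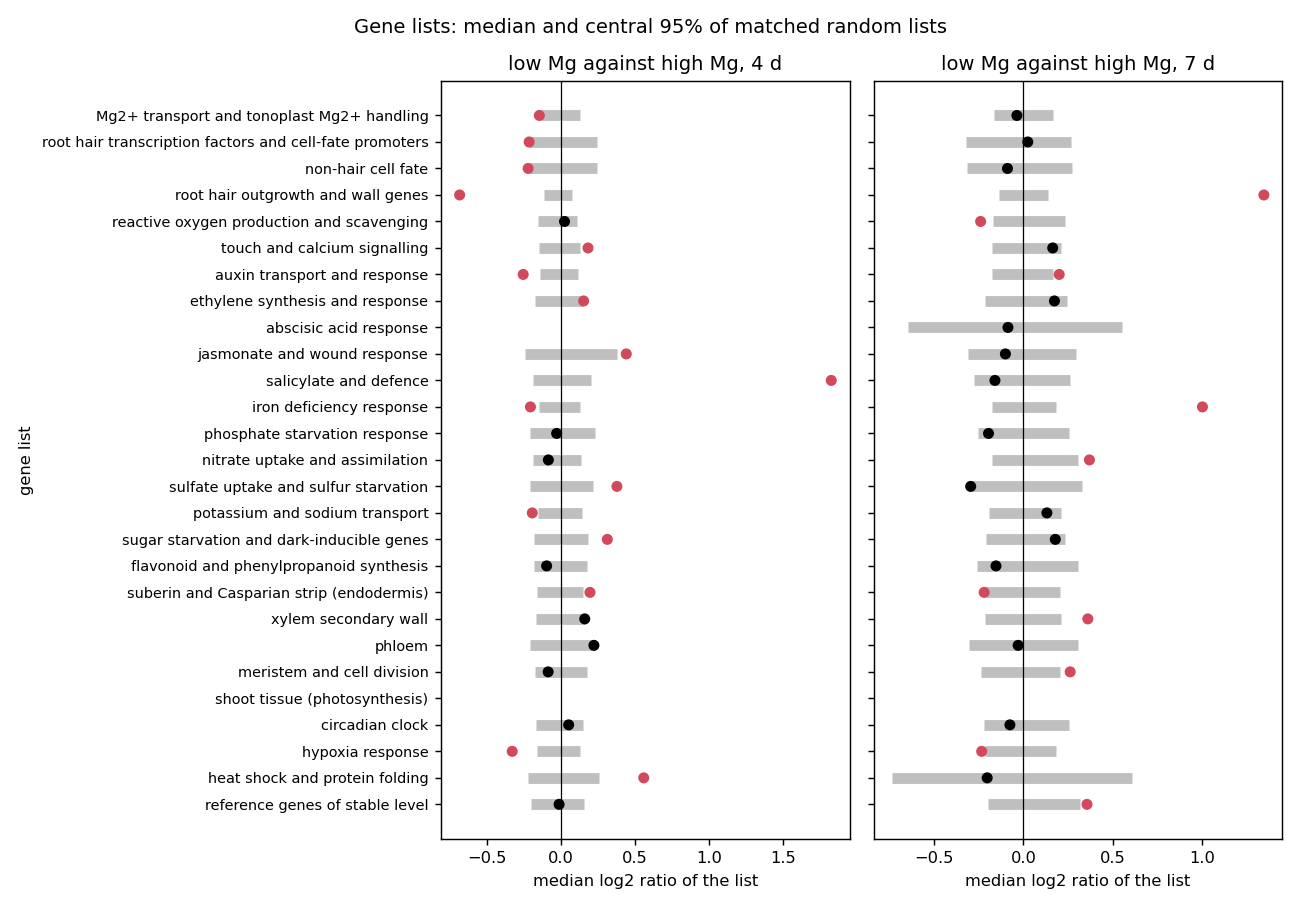
Median log2 ratio of each gene list (horizontal axes; lists on the vertical axis) for low against high Mg at 4 d (left) and at 7 d (right), with grey bars for the central 95% of 10000 matched random lists and red points for medians outside them. Outside lie 16 of 25 lists at 4 d, and 10 of 26 at 7 d; medians for ethylene, heat shock, jasmonate, suberin, sugar, sulfate and touch at 4 d turn negative under the TPM rescaling, and of these only ethylene and heat shock then lie within the range.

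Low and high Mg differed in part in the same genes on the 2 days, and in part in opposite ways. Genes higher in low Mg on both days included RTFL12, CYP71B22, the phloem lectin gene PP2-A4, CYP82C2, the glutamate receptor GLR2.3, EXO and the polygalacturonase inhibitor PGIP1. EXO stood at 106 and 108 FPKM in low Mg against 42.6 and 42.4 FPKM in high Mg at 4 d and 7 d. Lower on both days were TAT3, HAK5, AIR1, the glutathione transferase GSTU8 and the triterpene genes CYP705A5, CYP705A12 and CYP708A2. GSTU8 stood at 29.7 and 23.9 FPKM in low Mg against 191 and 93.9 FPKM in high Mg. MAPR2, listed near 0 in low Mg, stood at 3.80 and 19.1 FPKM in high Mg.

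Over 16678 genes the ratios of both days correlated at Pearson's r of -0.02 and Spearman's rho of -0.05 across genes, with the same sign in 47.1%. On both days, 75 genes were at least 2-fold higher and 87 at least 2-fold lower in low Mg. These 162 genes compare with 25.4 for independent lists. A further 146 genes lay 2-fold apart in opposite ways, against 27.8 for independent lists: 100 were higher in low Mg at 4 d and lower at 7 d, and 46 the reverse. An excess both ways, with r of -0.02, can come from genes whose values vary between any libraries. Neither overlap is therefore assigned to Mg.

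**Figure D4:**
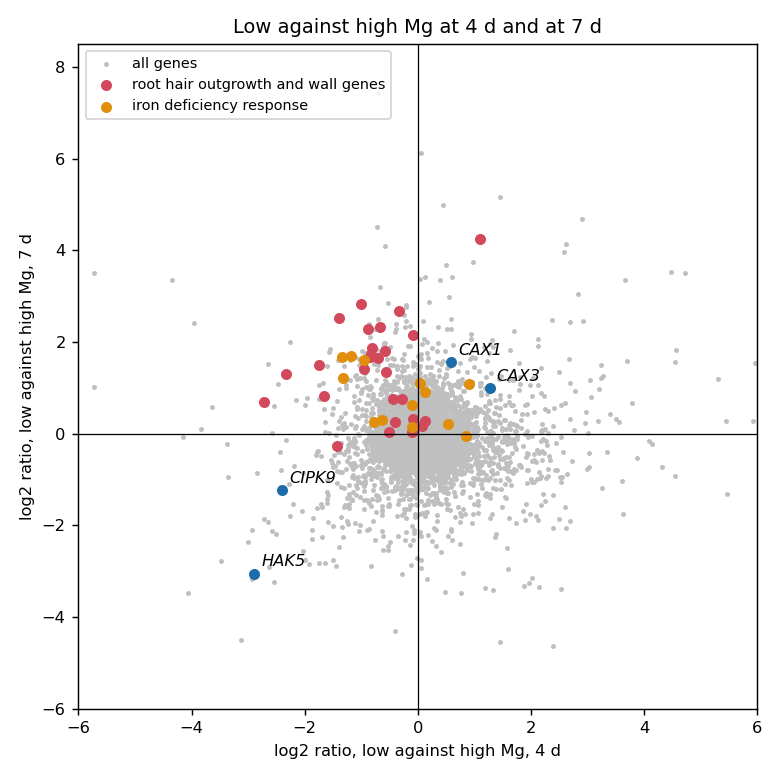
Log2 ratio of low to high Mg at 4 d (horizontal axis) and at 7 d (vertical axis) for 14843 genes measured in both comparisons (grey; 22 lie outside the axes), with root hair outgrowth genes in red, iron deficiency genes in orange and HAK5, CIPK9, CAX1 and CAX3 in blue. HAK5 and CIPK9 are lower and CAX3 is higher in low Mg on both days, while most root hair genes are below 0 at 4 d and above 0 at 7 d.

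Low and high Mg were also set side by side against the shared control at 4 d. PHT1;3 was listed at 0 in both treatments and at 47.2 FPKM in the control, a difference that fragments shared with its paralog PHT1;1 could also give. The other genes picked as lying the same way were short RNA genes, whose values stand for 1 or a few fragments and are not given. Opposite ways were taken by the defence genes TIR, SIB1 and MYB15, the triterpene synthase BARS1 and the calcium sensor CBL8. MYB15 stood at 51.9 FPKM in low Mg, 23.0 in the control and 7.01 in high Mg, and CBL8 at 1.69, 5.31 and 13.9 FPKM.

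In both treatments 132 of 16181 genes were at least 2-fold higher than the control and 196 lower, 328 in all, and 29 lay in opposite ways. Independent lists would share 19.3 genes in the same way. Pearson's r of the ratios was 0.53 and Spearman's rho 0.51 across genes, the covariance 0.25 and the share of the same sign 68.9%. A simulation of 3 libraries that share a control, with noise resampled from the observed ratios, gave r of 0.49, a covariance of 0.23, 66.7% of the same sign, 412 genes in the same way and 14 in opposite ways. That noise holds any effect of Mg, and it gave more 2-fold genes for low Mg (516 higher and 490 lower) than were observed over these genes (355 and 269). How much of the overlap comes from the shared control is left open.

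The 7-d libraries against the 4-d libraries describe time within each Mg level, and time is not separable here from other differences between the days. The tools used for the 7-d samples are not given in the sources used here, and organelle genes differed between the days. Chloroplast genes other than ATCG00760 summed to 297 FPKM in low and 389 FPKM in high Mg at 7 d. At 4 d they summed to 2780 and 3187 FPKM. Mitochondrial genes summed to 1284 and 1234 FPKM at 7 d, against 6345 and 5430 FPKM at 4 d. The cause of these differences was not tested. Clock genes differed in both Mg levels: CCA1, a morning clock gene, stood at 228 FPKM in low Mg and 256 FPKM in high Mg at 7 d, against 0.201 and 0.172 FPKM at 4 d. TOC1, an evening clock gene, was lower in both, at 19.1 against 57.7 FPKM in high Mg. Root hair outgrowth genes were lower at 7 d than at 4 d in high Mg, with 20 of 28 at 2-fold and a median of -1.76, and higher in low Mg, with 7 of 29 higher, 1 lower and a median of 0.62. EXT12 stood at -4.72 in high Mg, and COW1 at 1.35 in low Mg.

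In low Mg 652 of 16182 genes were at least 2-fold higher at 7 d and 2085 lower, with a median of all genes of -0.16. In high Mg the counts were 747 and 1819 of 16081 genes, with a median of -0.15. Across 16678 genes the time ratios of low and high Mg correlated at r of 0.55 and rho of 0.62, with 1398 genes 2-fold apart in the same way, against 268 for independent lists, and 140 in opposite ways. The TPM rescaling moved the medians of all genes by 1.92 in low Mg and 1.34 in high Mg. Upper-quartile scaling moved them by 0.14 and 0.18, and median centring by 0.16 and 0.15. TPM without AT2G01021, chosen after results were seen, moved them by 0.42 and 0.44. With it 60.3% of the 2-fold genes in low Mg and 70.4% in high Mg were higher at 7 d, against 23.8% and 29.1% without rescaling, so which direction prevails between the days depends on scaling. The time ratios also rose with exon length, a trend looked at after results were seen. Among genes of known exon length, 2719 were 2-fold apart in low Mg and 2543 in high Mg. With the trend taken out the numbers were 2133 and 2012, which can include genes short of 2-fold before. The random lists are not matched on length.

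Medians outside the random range in both Mg levels belonged to the clock list (-1.25 in low and -1.28 in high Mg), reactive oxygen (-1.05 and -0.75) and hypoxia genes (-0.72 and -0.80), all 3 turned positive by the TPM rescaling, under which only reactive oxygen genes in high Mg came to lie within the range. Heat shock (-2.74 and -2.26), potassium (0.69 and 0.35) and iron genes (0.24 and -0.77) also lay outside in both, the iron median in high Mg being turned positive by that rescaling but still below the range. The clock list held 4 of 14 members higher and 7 lower in low Mg, and 4 higher and 8 lower in high Mg, LHY at 7.39 and 7.30 among the first. In low Mg alone the salicylate list lay outside (-1.33, WRKY70 at -2.27). In high Mg alone the auxin list (-0.64) and root hair transcription factors (-1.18, LRL3 at -2.09) lay outside. The salicylate, auxin and transcription factor medians turned positive under the TPM rescaling and stayed below the range. Jasmonate (0.78, JAZ10 at 1.38) and sugar starvation genes (0.44, TPS11 at 1.77) lay above the range in high Mg. With a filter of 1 FPKM the jasmonate median was -0.0563, within the range. The Mg2+ transport list lay within the range at 0.15 in low Mg, with CIPK3 at 1.09, and at -0.07 in high Mg, and non-hair fate genes at -0.27 and -0.25 lay within it as well. Members named for this comparison are outside the rule and were chosen after their values were seen.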

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

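The tests of scaling, of the share of epidermis and of exchanged labels were chosen only after the result of the root hair genes was seen.

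Root hair wall genes stood on opposite sides on the 2 days: the median log2 ratio of low to high Mg was 2.03 higher at 7 d than at 4 d. EXT12 stood at -2.33 at 4 d and 1.31 at 7 d, EXPA7 at -0.95 and 1.40, and LRX1, a wall protein of growing hairs, at 12.6 FPKM in high Mg against 46.3 FPKM in low Mg at 7 d. Of 5 lists outside the random range on both days 4 were on opposite sides, and the other 3 were auxin, iron and suberin genes.

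Under 4 other scalings the root hair median stayed between -1.36 and -0.66 at 4 d, and between 1.30 and 1.34 at 7 d. This could not decide on scaling, since none moved all genes by enough to bring either median to 0. The largest shifts of all genes were -0.66 at 4 d, away from 0, and -0.07 at 7 d. A shift of all genes would move random lists as well, among which the medians lay at percentile 0 and 100. Those percentiles argue against such a shift as the source of either side. A different share of epidermis in the roots would move the non-hair fate genes the same way only if they mark that tissue as a whole, which was not checked. Their median was -0.0887 at 7 d, far from 0.67, the hair median divided by 2. This argues against a different share of the cells that express these fate genes at 7 d. It leaves open the share of other epidermal cells, such as mature hair cells. At 4 d their median was -0.22 beside -0.34, and share and regulation cannot be told apart. Exchanged labels of low and high Mg on 1 of the days cannot be told apart from a real reversal either, with 146 genes in opposite ways and 162 in the same way. Libraries of further plants would be needed to separate these.

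The auxin list, with LBD29 lower in low Mg at 4 d, had a median 0.46 higher at 7 d than at 4 d, and this difference was not tested further. With a filter of 20 FPKM the auxin median at 7 d lay within the random range. For the iron list, led by IRT1 and FRO2, the median was 1.21 higher at 7 d, and the cause was not tested. Under the TPM rescaling the iron median at 4 d lay within the random range. Suberin genes of the endodermis had a median lower at 7 d than at 4 d, by a log2 difference of -0.41. With a filter of 20 FPKM the 7-d median of suberin genes was 0.28, on the same side as at 4 d, so this reversal depends on the filter. The suberin median at 4 d lay within the random range with that filter.

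Chloroplast genes summed to 6749 FPKM in low Mg and 8207 FPKM in high Mg at 4 d, above the 4388 FPKM of the control, but ATCG00760, a ribosomal protein gene of the plastid, stood at 3969 and 5020 FPKM against 1065 FPKM. Its value was that of ATCG00065 in the control and 4 times that of ATCG00065 in low Mg, steps that 1 and 4 fragments on a very short gene would give, so the difference in the sums would rest on a few fragments. Without it the sums were 2780 FPKM in low Mg and 3187 FPKM in high Mg, below the 3324 FPKM of the control. Plastid genes were left out of the comparisons, and this difference was not tested.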

How the results depend on the processing

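The tests with TPM without AT2G01021 and with protein-coding genes of 500 nt or more alone were chosen only after results were seen. The series' matrix held the same values as the sample tables, so it gave no alternative result.

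Rescaling to the same nuclear sum (TPM) shifts all genes, because AT2G01021 takes a different share of the summed FPKM of each library. The fragments behind that share were not estimated for so short a locus. The TPM values thus show how far this locus moves the ratios, and are not taken as a better scaling. Of the ratios of named genes 266 reached 2-fold without the rescaling and 176 with it. This drop is not due to that shift alone, since genes below the filter after rescaling have no ratio and are not counted. A pseudocount of 5 left 221 at 2-fold, moved 138 ratios by more than 1.5-fold and kept 128 within it. One of 0.1 moved 94 and kept 172. TPM moved 90, turned 1 and kept 103, the other ratios having no value under its filter. By TPM CML9 in high Mg against the control went from -1.09 to 0.19. Against the control, the medians became 0.28 for root hair outgrowth and 0.0415 for nitrate genes in low Mg. In high Mg they became 0.97 for nitrate and 0.97 for phloem, 0.96 for suberin, 0.88 for sugar starvation, 0.87 for phosphate and 0.49 for salicylate genes.

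For low against high Mg at 4 d the same rescaling gave -0.62 for ethylene, -0.52 for suberin, -0.46 for heat shock, -0.46 for sulfate, -0.37 for sugar starvation, -0.37 for touch and -0.33 for jasmonate genes. For 7 d against 4 d in low Mg it gave 1.32 for clock, 1.26 for hypoxia, 1.11 for reactive oxygen and 1.03 for salicylate genes. In high Mg it gave 0.83 for auxin, 0.72 for reactive oxygen, 0.64 for hypoxia, 0.61 for iron and 0.44 for clock genes, and 0.55 for root hair transcription factors. Since the rescaling moves all genes, the place among random lists is the better measure: of the lists outside the random range that it turned, only ethylene and heat shock genes in low against high Mg at 4 d, suberin and phloem genes in high Mg against the control and reactive oxygen genes at 7 d against 4 d in high Mg came to lie within the random range. In the 4 comparisons of Mg levels 49 lists lay outside it, and 40 did under TPM. Without turning, Mg2+ transport, iron, non-hair fate and root hair transcription factor genes in low against high Mg at 4 d, and auxin genes in high Mg and xylem genes in low Mg against the control, also came to lie within it. Phosphate genes in low Mg against the control had too few measured members under TPM, and flavonoid genes in high Mg and suberin genes in low Mg came to lie outside. Genes that drop below the filter under TPM can change the members of a list. A change of place under TPM therefore need not come from the shift of all genes. Without AT2G01021 in the sum, TPM left each list median that lay outside the random range on its side.

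The filter turned few lists that lay outside the random range, and the cause was not tested. With one of 20 FPKM 35 lists lay outside instead of 49: in low against high Mg at 4 d Mg2+ transport, ethylene, suberin, non-hair fate and root hair transcription factor genes came to lie within the range, and at 7 d auxin, hypoxia and meristem genes. Against the control the same held for phosphate and xylem genes in low Mg and for auxin, phloem, phosphate, reactive oxygen and suberin genes in high Mg, while flavonoid genes in high Mg came to lie outside. The iron median in low Mg against the control was -0.0440 without a filter and -0.0440 with 1 FPKM, and in high Mg -0.11 and -0.14, all within the random range. A filter of 1 FPKM gave -0.0563 for jasmonate genes at 7 d against 4 d in high Mg, within the range. One of 20 FPKM gave 0.28 for suberin genes in low against high Mg at 7 d, above the range.

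Numbers of 2-fold genes depend on filter, threshold and scaling by construction. For low Mg against the control 608 became 401 with a pseudocount of 5, 367 with a filter of 20 FPKM and 193 at 4-fold. For high Mg against the control 1014 became 570 with that filter, 7728 by TPM and 368 at 4-fold. Low against high Mg at 4 d went from 870 to 508, 1349 and 299 in the same order. At 7 d, 902 became 560 with a pseudocount of 5, 466 with the filter and 273 at 4-fold.

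For 7 d against 4 d, 2737 genes in low Mg became 1781 with the filter of 20 FPKM, 13651 by TPM and 738 at 4-fold, and 2566 in high Mg became 1698, 10220 and 625. Genes 2-fold apart the same way in low and high Mg against the control went from 328 to 192 with a pseudocount of 5, 199 with the filter and 97 at 4-fold. Those apart the same way on both days went from 162 to 79, 94 and 33.

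The share of 2-fold genes that were higher moved with scaling. By TPM it went from 56.4% to 86.9% for low Mg and from 39.6% to 98.8% for high Mg against the control, and from 67.2% to 10.9% for low against high Mg at 4 d. For 7 d against 4 d in low Mg it was 23.8%, and 34.9% with median centring, 34.4% with upper-quartile scaling, 98.9% by TPM and 60.3% by TPM without AT2G01021. In high Mg it was 29.1%, and 41.1%, 44.0%, 98.0% and 70.4% in that order.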

Other observations

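The test of the trend with transcript length, and the sets of triterpene and salicylate-linked genes, were chosen only after the results were seen, while the tests of time of day, copper and zinc were set before their values were seen. Counts and medians of the triterpene and salicylate-linked sets follow in part from that choice and lend it no support.

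Genes of the thalianol and marneral clusters, a pair of root triterpene gene groups that lie apart on chromosome 5, were higher in high Mg. Of the 5 measured genes among THAS1, CYP708A2, CYP705A5, MRN1, CYP71A16 and CYP705A12, all 5 were at least 2-fold higher in high Mg than in the control at 4 d, with a median of 2.77. In low against high Mg all 5 were lower at 4 d (median -2.03), and 4 of 4 measured were lower at 7 d (-2.33). CYP705A12 stood at 33.4 and 37.9 FPKM in high Mg against 7.44 and 5.62 FPKM in low Mg on the 2 days.

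A set of regulators linked to salicylate, a defence hormone, differed in opposite ways on the 2 days. Of NIMIN1, NIMIN-2, NIMIN-3, WRKY51, WRKY62, EDS16 and FMO1, all 7 were at least 2-fold higher in low than in high Mg at 4 d (median 1.36), and 6 of 6 measured were lower at 7 d (-1.25). EDS16, which encodes the isochorismate synthase of salicylate synthesis, stood at 19.8 against 7.22 FPKM at 4 d and at 4.34 against 11.2 FPKM at 7 d. The salicylate and defence list fixed beforehand showed no such reversal: its median was 1.82 at 4 d, above the random range, but -0.16 at 7 d, within it, with 0 of 7 members at 2-fold.

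Copper-linked genes stood out in low Mg at 7 d, where COPT2, FRO4, FRO5 and FSD1 were high and CSD1 and CSD2 low, the pattern of plants short of copper, in which iron superoxide dismutase replaces the copper/zinc enzyme. Further genes raised by copper shortage had a median of 1.95, with ZIP2 at 2.85, YSL2 at 1.95 and CCH at 1.48, and targets of copper-responsive microRNAs had a median of -0.97. A low copper status may therefore lie behind it, but genes raised by zinc shortage also had a median of 1.60, with ZIP9 at 1.90 and ZIP3 at 1.77, so a general shortage of metals would fit as well. Compared afterwards, ZIP2, YSL2 and CCH were higher at 7 d than at 4 d in low Mg by 3.004, 2.42 and 2.96 and ZIP4 by 2.02, but ZIP3 and ZIP9 only by 0.89 and 1.04, being lower in high Mg (-1.53 and -1.47). In high Mg the ratios of 7 d to 4 d were -0.38 for ZIP2, 0.55 for YSL2 and 1.28 for CCH. FSD1 and FRO4 stood at 2.08 and 2.46 there, but COPT2 at -0.17, CSD1 at -0.66 and CSD2 at -0.88. Part of the copper pattern thus rose at 7 d in high Mg too. The tests leave a low copper status and a general shortage of metals both open, and the metal content of the roots was not analysed here.

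Clock genes differed between the days in both Mg levels, with CCA1 and LHY high at 7 d and GI, TOC1 and ELF4 high at 4 d. The difference in phase may come from roots taken at different times of the day: further morning-phased genes less evening-phased genes gave 4.77 in high Mg and 6.34 in low Mg. A trend of the time ratio with transcript length, at Spearman's rho of 0.39 in low Mg and 0.32 in high Mg across genes, was argued against as the source, since the clock list kept a median absolute log2 ratio of 3.303 without it. Time of day would reach other genes that cycle through the day, and which part of the 7 d to 4 d differences it accounts for was not tested. Comparisons within a day are spared it only where both libraries were taken at the same hour, which the labels do not give.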
